A study of Mus musculus with 18 samples.

How the data were processed

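The series holds 18 ChIP-seq libraries from mouse cells. Lamin B, a protein of the nuclear lamina that lines the inner nuclear membrane, was immunoprecipitated from wild-type embryonic stem cells (ESC, 2 libraries) and from cardiomyocytes derived from them and collected on day 10 of differentiation (CM, 2 libraries). H3K9me2, the dimethylated form of a histone H3 lysine that is typical of repressed chromatin, was immunoprecipitated from the same cell types (2 libraries each). A further ESC line carried floxed Hdac3 alleles, which encode a histone deacetylase, and a tamoxifen-inducible Cre. It gave 2 Lamin B and 2 H3K9me2 libraries without tamoxifen and 2 Lamin B libraries after deletion with 1 µg/ml tamoxifen for 24 h. Each of these 4 cell states also had 1 input library. Groups were taken from the titles and genotypes in the labels, which call the libraries of a group biological replicates.

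The values used were 4 lists of enriched domains, 1 for each combination of cell type and antibody. Reads had been processed with STAR, Picard and deepTools, and the genome build was mm9, per the submitters' processing notes, which give no versions. The authors' track headers carry the settings g 10, an automatic bin width and a false discovery rate of 5%. The domain caller is not given in the sources used here, and neither is the meaning of these settings beyond their names. Each deposited list gives the start and end of every domain and a score, which is the authors' own value per domain with a scale that is not given in the sources used here. The score grew with domain length in each list (Pearson's r across domains 0.944 to 0.963, over domains that are not independent replicates) and served only to rank and filter domains within a list. Every domain edge lay on a fixed grid, with bins of 9 kb in the ESC Lamin B list, 11 kb in the CM Lamin B list, 10 kb in the ESC H3K9me2 list and 20 kb in the CM H3K9me2 list.

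Each list is named by several libraries. Per the labels, the ESC Lamin B list is named by 6 libraries, 2 wild-type, 2 with floxed Hdac3 and no tamoxifen, and 2 with Hdac3 deleted. The ESC H3K9me2 list is named by 4 libraries, 2 wild-type and 2 with floxed Hdac3, and each CM list by 2 wild-type libraries. Whether all of these libraries entered the list, and how they were combined, is not given in the sources used here, so an ESC value may stand for wild-type cells alone or for a mixture with the Hdac3 line. The lists hold no value per library, so the spread between replicates and the sequencing depth are unknown, and no test of cell type could be made. Separate values of the Hdac3-deleted cells, and the input libraries, were not analysed here.

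Domains were placed on an exact 1 kb grid with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. The span of a chromosome ran from the first domain start to the last domain end over the 4 lists, which gave 2557 Mb over 21 chromosomes. Lists were compared by the Jaccard index, the sequence in both lists divided by the sequence in either. Its position was tested against 10000 random rotations of a list along each chromosome, which keep the lengths and spacing of domains. The p-values are two-sided permutation p-values, of which 0.0002 is the smallest that these rotations can give. They test whether domains of both lists lie in the same places, not whether cell types differ. Percentile intervals at 95% came from 10000 resamples of the chromosomes and cover variation between chromosomes only. A domain counted as shared when at least 50% of its length lay in the other list, and shares of domains carry Wilson 95% intervals. These treat domains as independent and cover counting error only.

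Sequence in a domain of a single cell type was called ESC-only or CM-only, and stretches of at least 100 kb were counted. To ask whether both antibodies differed in the same places, the share of ESC-only Lamin B sequence that was also ESC-only for H3K9me2 was set against that share in Lamin B sequence common to both cell types. The positions of the H3K9me2 difference were rotated 10000 times, and the same was done for CM-only sequence and for opposite directions. Benjamini-Hochberg adjustment, with statsmodels 0.14.6, ran over the 4 pairs of lists, over the 4 joint differences and over 12 tests of chromosome ends. Figures were drawn with matplotlib 3.10.9, and scipy 1.17.1 gave the intervals of shares and the correlations. On simulated data with the 771 ESC Lamin B domains, the rotation test gave a p below 0.05 in 6.00% of 200 independent pairs and in 100% of 100 pairs that shared 20% of their domains, with 1000 rotations per pair. Simulated domains were placed at random along each chromosome, so they lack any large-scale clustering that the real lists may share. Only the overlap of a pair of lists was simulated, not the joint differences or the chromosome ends. The simulated rate therefore does not vouch for the p-values of the real lists. In a simulated loss, 100% of the lost sequence was recovered, which checks the arithmetic of subtracting lists and not the calling of domains.

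The comparisons of pairs of lists, the joint test of ESC-only sequence, the lists of alternatives and the rule for named regions were fixed before the data were examined. The joint tests of CM-only sequence and of opposite directions were added later. The tests of chromosome ends, of the distal X, of X against autosomes, of the correlation between chromosomes and of copies on distal chromosome 3 were chosen after their results were seen. The regions named are the 5 longest ESC-only and the 5 longest CM-only stretches for each antibody. Tests of gene lists and gene families, and names of genes, had also been planned for the case that an annotation of mm9 was in hand. The gene table in hand was of GRCm38.p6, and on 8 of the 21 chromosomes the farthest domain end lay past the last gene of that table. Coordinates of different builds were not mixed, so genes are not analysed here and regions are given by their mm9 coordinates, counted from 1. Alternatives covered a filter at each list's own median score, merging across short gaps, shortened domains and autosomes alone. They also covered other minimum lengths of a stretch and other overlaps that count as shared. A common 20 kb grid and the omission of distal chromosome 3 were added after the data were seen.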

Results

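Lamin B and H3K9me2 were mapped by ChIP-seq in mouse ESC and in cardiomyocytes differentiated from them for 10 days, to ask which lamina-associated regions and which H3K9me2 domains differ between these cell types. The data compared were 4 domain lists, 1 for each cell type and antibody and each named by several libraries in the labels. No list had replicates, so the differences between cell types carry no replicate error and no depth. Lamin B domains numbered 771 in ESC and 933 in CM, with median lengths of 459 kb and 374 kb. H3K9me2 domains numbered 2680 in ESC and 1240 in CM, with median lengths of 130 kb and 440 kb. Most covered sequence lay in long domains, since domains of at least 1 Mb held 82.8% of the ESC and 82.2% of the CM Lamin B sequence, and 63.7% of the ESC and 77.0% of the CM H3K9me2 sequence. The longest domain of every list lay on chromosome 14, where CM Lamin B covered 14:80498001–118173000 (mm9) and ESC Lamin B 14:80676001–118179000. CM H3K9me2 covered 14:80180001–118180000 as a single domain, whereas the longest ESC H3K9me2 domain ended at 99420000.

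The lamina-associated part of the genome was largely the same in ESC and CM. Lamin B domains covered 1117 Mb in ESC and 1213 Mb in CM, or 43.7% and 47.4% of the span of the chromosomes. Of the ESC Lamin B sequence, 97.0% (95% interval over chromosomes 96.0 to 97.8) also lay in CM domains, and 89.3% (87.4 to 91.2) of the CM sequence lay in ESC domains. CM-only Lamin B sequence came to 129.8 Mb, 3.82 times the 34.0 Mb of ESC-only sequence. Of the ESC Lamin B domains, 716 of 771 (92.9%, Wilson interval 90.8 to 94.5) were shared with CM, and of the CM domains 649 of 933 (69.6%, 66.5 to 72.4) were shared with ESC. Domains that were not shared tended to be shorter in both lists. Their median was 176 kb in CM against 649 kb for shared ones, and 171 kb in ESC against 522 kb. Of the domains that were not shared, 7 in CM and 1 in ESC were at least 1 Mb long, with the longest at 5236 kb in CM.

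The Jaccard index of the Lamin B lists was 0.869 (0.850 to 0.887), against 0.308 ± 0.0159 (SD) for 10000 random rotations (two-sided permutation p = 0.0002, also 0.0002 after Benjamini-Hochberg adjustment over 4 pairs of lists). In stretches of at least 100 kb, ESC-only Lamin B came to 24.4 Mb in 107 stretches and CM-only Lamin B to 110.1 Mb in 406 stretches. Of this CM-only sequence, 50.3% lay apart from any ESC domain, 33.1% extended an ESC domain on a single side and 16.6% bridged a pair of ESC domains. ESC-only sequence split differently, with 30.6% apart from CM domains, 28.6% beside 1 domain and 40.9% between CM domains. Stretches of at least 500 kb were few, 6 ESC-only and 34 CM-only, and held 4.47 Mb and 29.6 Mb.

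The longest CM-only Lamin B stretch was 3:154363001–159599000 (mm9), 5.24 Mb that ran to the last domain end of chromosome 3. ESC had no Lamin B or H3K9me2 domain there, and CM H3K9me2 covered 60.7% of it. The copy number of this segment in the libraries was not analysed here. The next longest were 10:128469001–129976000 (1.51 Mb), also at the last domain end of its chromosome, X:4995001–6165000 (1.17 Mb), 9:27291001–28404000 (1.11 Mb) and 16:76113001–77166000 (1.05 Mb). H3K9me2 coverage of the chromosome 16 stretch was 17.8% in ESC and 100% in CM, whereas the chromosome 9 stretch was fully covered by H3K9me2 in both cell types. The chromosome 10 and X stretches had 81.0% and 62.4% H3K9me2 coverage in ESC and 98.9% and 98.3% in CM.

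The longest ESC-only Lamin B stretch, 12:120096001–121257000 (1.16 Mb), lay at the last domain end of chromosome 12, and H3K9me2 covered 87.9% of it in ESC and 86.1% in CM. X:160193001–160974000 (781 kb) and X:158873001–159445000 (572 kb) were also among the longest. ESC H3K9me2 covered 38.5% and 21.3% of them, and CM H3K9me2 9.48% and 12.6%. The other 2 were 7:96888001–97625000 (737 kb) and 2:135146001–135828000 (682 kb). On chromosome 2 the stretch had 20.5% H3K9me2 coverage in ESC and 0% in CM, and on chromosome 7 it had 26.1% and 36.9%. No annotation of this build was used, so the genes in these stretches are not given.

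**Figure D1:**
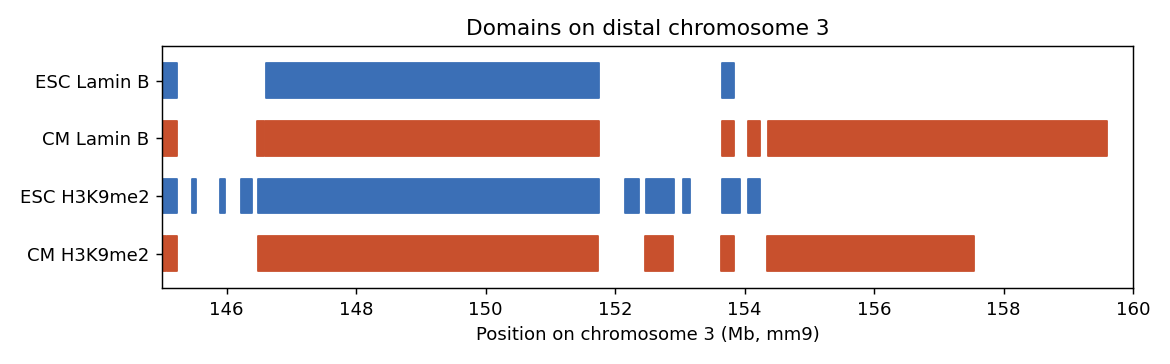
Domains of the 4 lists on distal chromosome 3, with the position in Mb (mm9) on the x axis and ESC lists in blue, CM lists in orange. Each bar is a domain, and the long CM Lamin B domain at 154363001–159599000 has no ESC domain of either antibody beneath or above it.

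H3K9me2 domains were also largely common to ESC and CM. They covered 1319 Mb in ESC (51.6% of the span) and 1407 Mb in CM (55.0%). Of the ESC H3K9me2 sequence, 95.1% (94.3 to 95.9) lay in CM domains, and of the CM sequence 89.2% (87.3 to 90.7) lay in ESC domains. CM-only H3K9me2 sequence came to 152 Mb, 2.38 times the 64.0 Mb of ESC-only sequence. ESC H3K9me2 domains were shorter and more numerous, and 2084 of 2680 (77.8%, Wilson interval 76.1 to 79.3) were shared with CM, against 1071 of 1240 CM domains (86.4%, 84.3 to 88.2) shared with ESC.

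The Jaccard index of the H3K9me2 lists was 0.853 (0.837 to 0.866), against 0.370 ± 0.0113 (SD) for random rotations (two-sided permutation p = 0.0002, adjusted 0.0002). In stretches of at least 100 kb, ESC-only H3K9me2 came to 28.7 Mb in 207 stretches and CM-only H3K9me2 to 94.7 Mb in 478 stretches. The kinds of stretch differed, since 48.7% of the CM-only sequence bridged a pair of ESC domains and 17.9% stood apart from them, whereas 86.4% of the ESC-only sequence stood apart from CM domains and 2.02% lay between them. The ESC list was divided into more and shorter domains, in bins of 10 kb against 20 kb in CM. A gap between ESC domains inside a long CM domain counts as a bridge. These kinds therefore cannot be told apart from the unequal division of the lists. The ratio of CM-only to ESC-only sequence in these stretches, 3.30, was 1.53 for domains at or above the median score, 1.94 after merging across gaps under 100 kb and 22.2 with 50 kb removed from each domain end. Its size therefore depended on how the domains were delimited. Its direction held under the score filter and after merging. Trimming takes more from a list with more and shorter domains, here the ESC list, so that alternative does not bear on the direction.

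The longest CM-only H3K9me2 stretch was 3:154340001–157540000 (3.20 Mb), inside the distal chromosome 3 segment without ESC domains. The others were 3:138740001–139490000 (750 kb), 7:11350001–12080000 (730 kb), 9:3860001–4540000 (680 kb) and 16:6960001–7580000 (620 kb). The chromosome 7 stretch lay in CM Lamin B over 100% of its length and in ESC Lamin B over 1.10%, while the chromosome 9 stretch lay in Lamin B domains of both cell types throughout. Lamin B covered 75.5% of the stretch at 3:138740001–139490000 in ESC and 82.0% in CM, and 0% and 17.9% of that on chromosome 16. ESC-only H3K9me2 stretches were shorter, the longest being 8:131260001–131720000 (460 kb), 5:27580001–27980000 (400 kb), 8:130890001–131170000 (280 kb), 19:28290001–28550000 (260 kb) and 11:105530001–105770000 (240 kb). The last of these was tied in length with at least 5 others. The stretch at 8:131260001–131720000 lay wholly in CM Lamin B and outside ESC Lamin B, and those on chromosomes 5 and 19 and at 8:130890001–131170000 lay outside Lamin B in both cell types.

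Lamin B domains lay mostly inside H3K9me2 domains in ESC and in CM. In ESC, 92.9% (91.6 to 94.1) of Lamin B sequence was also covered by H3K9me2, against 52.6% for rotated lists, and in CM 95.7% (94.9 to 96.5), against 56.4%. The converse share was smaller, with 78.7% (75.8 to 81.3) of H3K9me2 sequence inside Lamin B in ESC and 82.5% (79.8 to 85.2) in CM. The Jaccard index of the antibodies was 0.742 (0.718 to 0.763) in ESC and 0.796 (0.772 to 0.818) in CM, and rotated lists gave 0.318 ± 0.0133 and 0.354 ± 0.0128 (two-sided permutation p = 0.0002 and adjusted p = 0.0002 in both). All 4 lists together covered 1007 Mb (39.4% of the span), and 1037 Mb (40.5%) lay in none. A further 155 Mb (6.07%) was H3K9me2 in both cell types without Lamin B in either. Whether the overlap differed between ESC and CM was not tested.

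Part of the sequence that differed in Lamin B between ESC and CM also differed in H3K9me2 in the same direction. Of the CM-only Lamin B sequence, 25.3% was CM-only for H3K9me2, compared with 4.18% of the Lamin B sequence common to both cell types. Of the ESC-only Lamin B sequence, 12.2% was ESC-only for H3K9me2, compared with 0.875% of the common sequence. The common sequence had little room to differ, since 93.0% of it lay in H3K9me2 domains of both cell types. Of the sequence without H3K9me2 in ESC, CM had H3K9me2 on 65.1% where Lamin B was CM-only and on 68.5% where Lamin B was common. On this scale CM-only Lamin B therefore had no higher share than the common sequence. Both shares were above those where CM had no Lamin B domain, 15.2% where Lamin B was ESC-only and 6.52% where it was in neither cell type. Of the sequence with H3K9me2 in ESC, CM lacked it on 19.7% where Lamin B was ESC-only and on 23.0% where Lamin B was in neither, against 0.932% where it was common and 5.04% where it was CM-only. These shares of the sequence that could differ were computed without a test. Most of the differing sequence had the same H3K9me2 state in both cell types, since 58.0% of CM-only and 49.7% of ESC-only Lamin B sequence lay in H3K9me2 domains of ESC and CM alike, and 13.6% and 32.3% lay in neither.

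Without regard to that room, the difference between differing and common Lamin B sequence was 21.2 points for CM-only sequence (rotated 0.811 ± 1.02 SD) and 11.3 points for ESC-only sequence (0.307 ± 0.841). Both had a two-sided permutation p of 0.0002, or 0.00027 after Benjamini-Hochberg adjustment over 4 tests. The overlap itself was 32.9 Mb for CM-only and 4.15 Mb for ESC-only sequence, 3.64 and 4.38 times the rotated means (permutation p = 0.0002 in both). In opposite directions, CM-only Lamin B was ESC-only for H3K9me2 over 3.08% of its length, 2.20 points above the 0.875% of common sequence (adjusted permutation p = 0.00027), but this overlap was 1.30 times the rotated mean and missed the threshold (permutation p = 0.089). ESC-only Lamin B was CM-only for H3K9me2 over 5.77%, which differed from the common sequence by 1.59 points (adjusted permutation p = 0.084) and was 1.07 times the rotated mean (permutation p = 0.69). With 50 kb removed from each domain end the ESC-only difference was 4.31 points, and for domains at or above the median score 17.4 points, each with a permutation p of 0.0002.

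**Figure D2:**
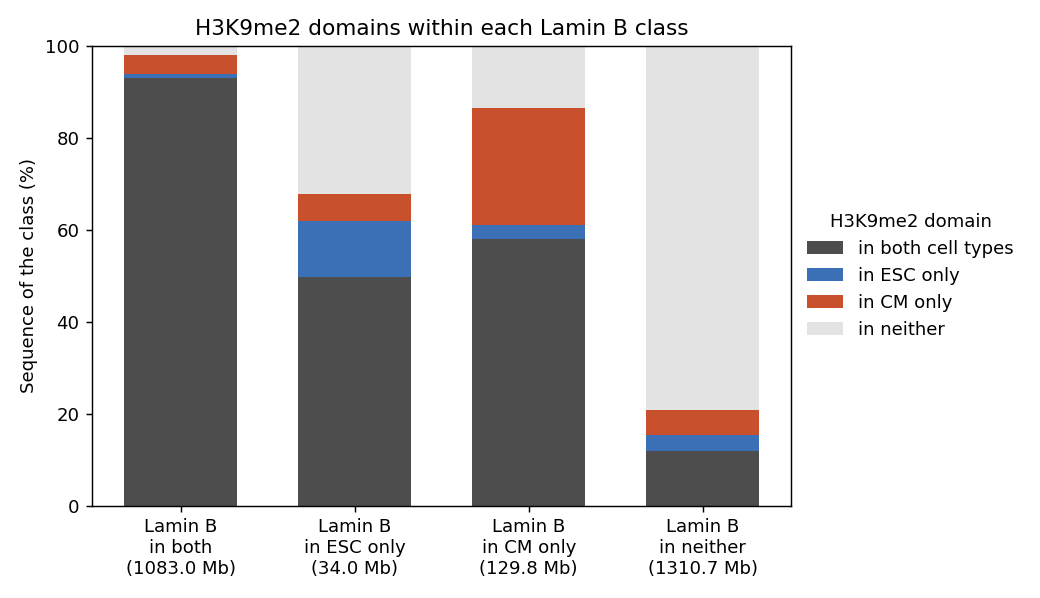
Stacked bars give the percentage of sequence in each Lamin B class (y axis) that lay in H3K9me2 domains of both cell types, of ESC only, of CM only or of neither, with the Mb of each class on the x axis. The CM-only H3K9me2 share is 25.3% in CM-only Lamin B sequence and 4.18% in the common sequence, of which 93.0% lies in H3K9me2 domains of both cell types.

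Lamin B coverage was higher in CM than in ESC on 18 of the 19 autosomes and on X. The mean difference over autosomes was 3.72 ± 2.91 percentage points (SD over 19 chromosomes, which are not replicates). It was largest on chromosome 3, at 51.7% in ESC and 61.7% in CM. That rank rested on the distal stretch, without which the difference was 6.87 points in place of 9.98, less than the 8.08 points of chromosome 16. Chromosome 11 was the exception, at 32.5% in ESC and 29.6% in CM. H3K9me2 coverage was higher in CM on 17 of the 19 autosomes, by a mean of 3.39 ± 3.61 points, and lower on chromosomes 8 and 11. Chromosome 16 stood apart, with 46.7% H3K9me2 coverage in ESC and 62.2% in CM, alongside 44.4% and 52.5% for Lamin B.

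The X chromosome had the highest Lamin B coverage of all chromosomes in both cell types. Lamin B covered 63.3% of X in ESC and 69.5% in CM, and H3K9me2 covered 61.9% and 67.5%. On all 19 autosomes H3K9me2 coverage exceeded Lamin B coverage in both cell types, and on X it did not. On Y, Lamin B covered 23.6% in ESC and 61.1% in CM, values that rest on a span of 2.90 Mb. The labels of libraries from a further ESC line, some with Hdac3 deleted, name the ESC lists too. Whether their reads entered these lists is not given in the sources used here, so the ESC values may stand for wild-type cells alone or for a mixture.

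**Figure D3:**
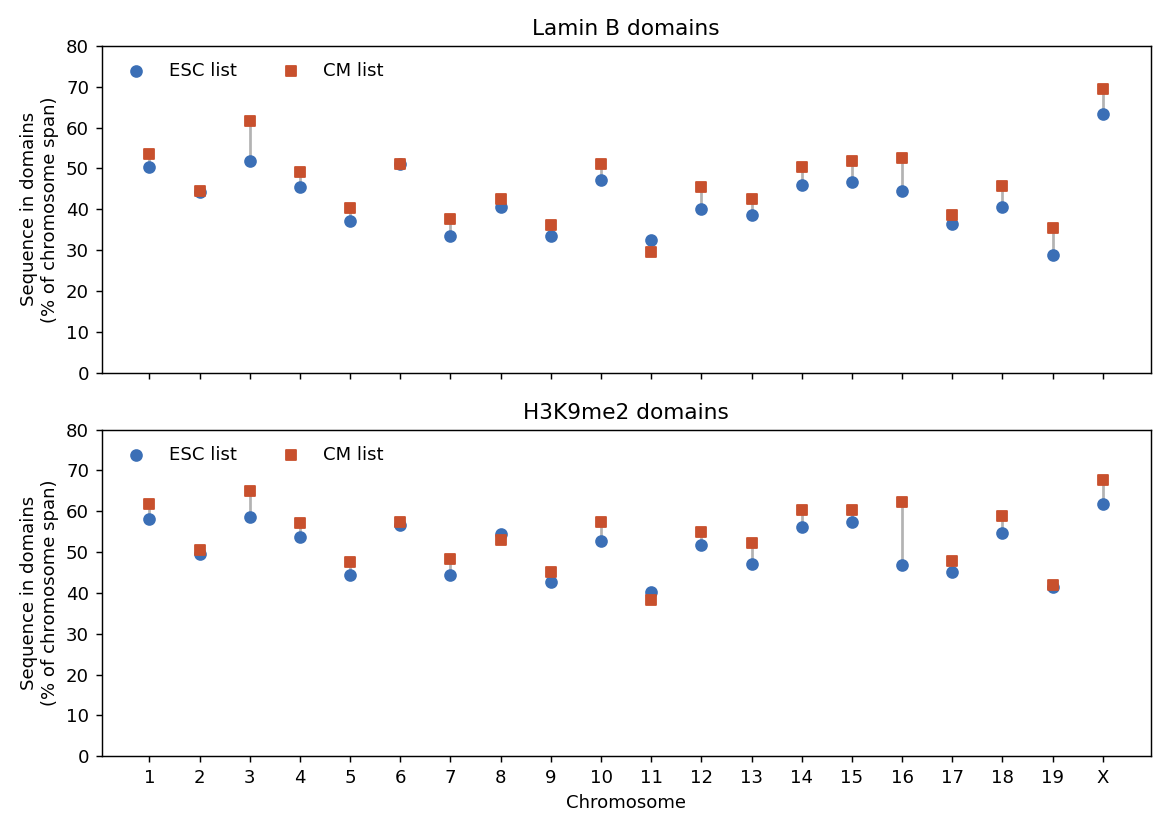
Percentage of the span of each autosome and of X in Lamin B domains (top) and H3K9me2 domains (bottom), with chromosomes on the x axis, ESC as blue circles and CM as orange squares. Of these chromosomes, 3 has the widest gap for Lamin B (51.7% and 61.7%) and 16 for H3K9me2 (46.7% and 62.2%).

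ESC-only Lamin B on X was concentrated at the distal end. The last 12 Mb of the span, X:154410001–166410000, held 3.31 Mb of ESC-only Lamin B and 0 Mb of CM-only Lamin B, which was 79.0% of the 4.20 Mb of ESC-only sequence on X. Of the 10 longest ESC-only Lamin B stretches in the genome, 4 lay between X:155683001 and X:163141000. This window was chosen after its values were seen.

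**Figure D4:**
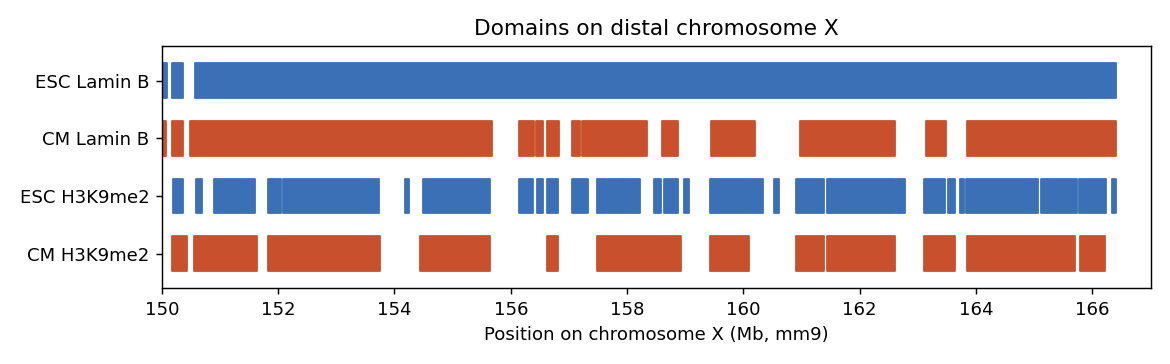
Domains of the 4 lists on distal chromosome X, with the position in Mb (mm9) on the x axis and ESC lists in blue, CM lists in orange. CM Lamin B is broken by gaps where ESC Lamin B is continuous, and these gaps make up the 3.31 Mb of ESC-only sequence in the last 12 Mb.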

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

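The common 20 kb grid and the omission of distal chromosome 3 were alternatives chosen after the data were seen; the others were planned. All 30 alternatives of the 4 overlaps and of the joint differences in the same direction kept their direction, each with a permutation p of 0.0002, the smallest possible here. The joint differences were again taken without regard to the little room that common Lamin B sequence had to differ. Shares of the sequence that could differ were not recomputed, so these alternatives do not bear on them. The joint differences in opposite directions were not recomputed under alternatives. CM-only exceeded ESC-only sequence in 8 of 8 alternatives for Lamin B (ratio 3.54 to 6.63) and in 7 of 7 for H3K9me2 (1.53 to 22.2). The amounts moved more. With 50 kb removed from each domain end, which leaves no domain of 100 kb or less, H3K9me2 stretches came to 8.67 Mb ESC-only and 192.2 Mb CM-only (ratio 22.2), against 28.7 and 94.7 Mb. Such trimming takes more from the ESC H3K9me2 list, whose domains were shorter and more numerous. For H3K9me2 this alternative is therefore no support for the direction. ESC-only H3K9me2 was 81.1 Mb for domains at or above the median score (ratio 1.53) and 52.5 Mb after merging across gaps under 100 kb (ratio 1.94), and the cause was not tested. The score filter cut each list at its own median, 4.06 for ESC and 9.97 for CM H3K9me2. Scores of different lists may not be on the same scale. Within each list the score grew with domain length, and median lengths were 130 kb for ESC and 440 kb for CM H3K9me2. The filter may therefore have dropped CM domains of lengths that were kept in the ESC list, which can itself add ESC-only sequence. By construction, the minimum length of a stretch also moved the amounts. At 50 kb, ESC-only H3K9me2 was 56.8 Mb. At 500 kb it was 0 Mb against 11.0 Mb CM-only, so no ratio could be given, and Lamin B came to 4.47 Mb ESC-only and 29.6 Mb CM-only. Under overlaps from any contact to 75% of a domain, shared domains ranged from 89.4% to 94.2% (ESC Lamin B), 61.2% to 72.8% (CM Lamin B), 77.0% to 78.2% (ESC H3K9me2) and 70.9% to 93.9% (CM H3K9me2). No paired analysis was possible because each list is given once for several libraries, so no library could be left out either. Alternatives planned for gene lists were not run, since no annotation of the build was used. Depth is unknown, so a missing domain may reflect a shallow library as well as a difference between cells. Filtering each list at its own median score moved ESC-only H3K9me2 from 28.7 to 81.1 Mb, but ESC-only Lamin B only from 24.4 to 31.2 Mb.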

Other observations

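The tests of chromosome ends, of the distal X, of X against autosomes, of the correlation between chromosomes and of copies on distal chromosome 3 were chosen after their results were seen; the other tests had their limits set beforehand. Mouse chromosomes have their centromere at the proximal end, and CM-only Lamin B was denser there. Within 5 Mb of the proximal end, 19.5% of the sequence without ESC Lamin B was CM-only, against 8.49% elsewhere, a difference of 11.0 points (rotated SD 3.00, permutation p = 0.0046, Benjamini-Hochberg adjusted p = 0.013 over 12 tests, higher on 16 of 20 chromosomes). Without chromosome 3 the difference was 11.5 points (adjusted permutation p = 0.0056). H3K9me2 gave 28.5% and 11.6% (17.0 points, adjusted permutation p = 0.0024, higher on 15 of 20 chromosomes). The distal ends did not pass the test for Lamin B (4.47 points, adjusted permutation p = 0.20) or H3K9me2 (-0.211 points, 0.98). Without chromosome 3 the distal differences were -1.69 points for Lamin B (adjusted permutation p = 0.59) and -3.83 points for H3K9me2 (0.20). Both ends together gave 7.80 points for Lamin B (adjusted permutation p = 0.013), but this rested on chromosome 3, without which it was 4.78 points (adjusted permutation p = 0.10). For H3K9me2 both ends together gave 8.05 points (adjusted permutation p = 0.014), and 6.12 points without chromosome 3 (adjusted permutation p = 0.048). Lists per library and the mappability of these ends, which would be needed to tell a difference between cell types from uneven mapping, were not used here.

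The last 12 Mb of X held 3.31 Mb of ESC-only Lamin B, against a median of 0.026 Mb and a highest value of 1.47 Mb in 2314 other windows of that length (percentile 100). The window was drawn around stretches already seen to be among the longest, so this rank restates the choice and does not show that X differs from the autosomes. Of the ESC Lamin B sequence on X, 87.6% lay in H3K9me2, below the autosomal median of 93.5% but not below chromosome 13 (87.5%), so whether X stands outside the autosomes in ESC stays open. In CM the share was 92.8%, below all 19 autosomes (lowest 93.9%, on chromosome 3). For the distal X, neither a difference between cell lines, should the ESC list hold more than the wild type, nor a local loss of Lamin B in CM was tested. Over the 19 autosomes, the difference between CM and ESC in Lamin B coverage went with that in H3K9me2 coverage (Spearman's rho 0.681, permutation p = 0.0019, and Pearson's r 0.686, permutation p = 0.0021). Without chromosomes 11 and 3, the farthest from the median for Lamin B, rho was 0.556 (permutation p = 0.022) and r was 0.644 (permutation p = 0.0048). Without chromosome 16, the farthest for H3K9me2, rho was 0.626 (permutation p = 0.0067) and r was 0.719 (permutation p = 0.00088). Without chromosomes 3, 11 and 16 together the relation missed the threshold, with rho at 0.468 (permutation p = 0.070) and r at 0.423 (permutation p = 0.10), so it rests in part on these chromosomes. Chromosomes are not replicate cultures, and a shared copy-number difference of a chromosome would move both antibodies as well.

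The 5.24 Mb CM-only stretch on distal chromosome 3 was the longest difference between ESC and CM in either antibody. Whether domains called more freely across the genome in CM could be its cause was examined in windows of its length. Of 4090 other such windows with at most 5% ESC Lamin B, over 20 chromosomes, 0% were more than 50% covered by CM Lamin B (median 0%, highest 41.5%), whereas at least 5% had been required. The stretch had been picked as the longest CM-only one and set the window length, so a low share elsewhere was likely beforehand. The windows also overlapped, and scattered short domains from freer calling would not reach 50%. This test therefore cannot decide on freer calling. A segment with more copies in the CM libraries could raise both antibodies and cannot be told apart from a change of the lamina. CM H3K9me2 covered 60.7% of the stretch, between the limits of 90% and 10% set for that test, and the input libraries that would decide were not used here.

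The ESC H3K9me2 list had 2680 domains and the CM list 1240. Rounding of domain edges to the coarser grid is argued against as the whole cause, since the ESC list put on the 20 kb grid still had 2.12 times as many domains (2624). That explanation was worded more narrowly after its result was seen, with its limit of 1.5 times unchanged, and calling in wider bins, which could join neighbouring domains, stays open. After merging across gaps under 100 kb the ratio was 1.498 (1528 against 1020), barely inside the limit set beforehand. Gaps under 100 kb thus account for part of the excess in number. Merging lowers the count of any list with close domains, so it does not show that these gaps lay inside longer domains. Of the ESC domains 583 of 2680 touched no CM domain, and of the CM domains 76 of 1240 touched no ESC domain. The merged ESC domains were still shorter, with a median of 350 kb against 640 kb in CM. Deeper or noisier libraries, and a real difference in continuity between ESC and CM, were not tested.

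Chromosome 16 had the widest H3K9me2 difference of the autosomes, 15.5 points. A few long stretches are argued against as its cause, since the 5 longest held 18.7% of its CM-only H3K9me2. Such a low share was not particular to chromosome 16. Among autosomes it ran from 16.6% on chromosome 1 to 44.0% on chromosome 19. Gains exceeded losses in 10 of 10 equal segments of chromosome 16. The 18 other autosomes had a median of 7.50 such segments (range 3 to 10, with 1 chromosome at 10). Chromosome 16 was picked for its wide difference, with 14.9 Mb of CM-only and 0.29 Mb of ESC-only H3K9me2. A net gain in most segments was therefore likely beforehand. It cannot tell a shift along the whole chromosome from gains scattered along it. A different number of copies of chromosome 16 between the libraries would be such a shift, and so would a change of its chromatin in CM, and neither was tested.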
